A study of Mus musculus with 21 samples.

How the data were processed

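The series holds 21 mouse libraries in 7 groups of 3, made from polyadenylated RNA with a directional library kit. The group of each library was taken from its title. Culture time (10 to 14 days) and inhibitor time (48 h) come from the labels' protocols. The data are 3 tables of the authors' own comparisons, in the layout of a Cuffdiff gene table per the file headers. The table of 3 populations holds 3 pairs, and the other tables hold 1 pair each. Per the submitters' processing notes, the 9 libraries of the 3-population table were handled with FastQC 0.11.3, HISAT 0.1.6, StringTie 1.1.0, Cufflinks 2.2.1 and Cuffdiff, while the labels' description of the same libraries names a TopHat2 alignment. For the other 12 libraries, the submitters' processing notes name FastQC 0.11.2, cutadapt 1.5, TopHat2 2.0.13, featureCounts of Subread 1.4.2 and DESeq2 1.8.1. The deposited tables of these libraries have the Cuffdiff layout, so which tool made their p-values is not settled. The genome build was GRCm38 for all 21 libraries, per the same notes.

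Expression values are in FPKM per the file headers, as estimated by the authors over the replicates of a population. No value per replicate was analysed here. In the 3-population table the deposited FPKM columns hold whichever population the line names, so each value was assigned by the population name on its own line. Each log2 fold change was deposited by the authors as the log2 ratio of the FPKM values of a line. It was turned here so that it is positive where CD34a6, HFSC, CD34+ or dorsomorphin was higher than its counterpart. The p-value and q-value columns hold the authors' test and its adjusted value, and the smallest deposited p-value was 5e-05. The deposited q-values equalled a Benjamini-Hochberg adjustment of the deposited p-values over the tested loci of a table, pooled over the 3 pairs in the 3-population table, to within 5.3e-07. Read depth per library was unknown, so no counting interval or detection limit is given, and precision rests on the authors' test alone.

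A gene is a locus with its symbol as the tables give it, and the counts of genes higher and lower are counts of loci. Loci were compared with the gene annotation GENCODE vM21 by symbol. Of 13457 symbols of the 3-population table found there, 99.9% lay at a locus that overlapped the annotated gene and 49.6% had the same start and end. Starts in the tables count from 0 and are printed here counting from 1. Some loci span several genes, and the other genes are named beside some of the values concerned. The column named 3C_HFSC in the table of sorted culture fractions was read as the CD34+ fraction, because the labels describe that comparison as CD34+ against CD34neg. In the 3-population table bulk was read as total epidermal cells, and the names CD34a6 and HFSC were kept.

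The plan set before the data were examined had edgeR or limma-trend as tests and camera for gene lists, with the authors' comparison alone if the tables held no values per replicate. That last case applied. The calls are the authors' (adjusted p under 0.05), and no test of individual genes was made here. For gene lists, camera was replaced by a description. The median log2 fold, with a pseudocount of 1 FPKM, of a list's tested members was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins, for lists with at least 5 tested members. The rule that a median outside the central 95% of random lists is set apart was chosen after the tables were seen. A pseudocount of 1 understates the folds of low genes. Percentiles describe these tables and are no p-values, since genes are not replicates.

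The 29 lists, with 474 memberships of 444 genes, were fixed before the data were examined from general knowledge of skin, and include markers of fibroblasts, immune cells, melanocytes, endothelial and mural cells, Merkel cells, muscle and erythroid cells. Some genes stand in several lists, and the adhesion and basal lists share 5. Counts of members past the threshold are given over all genes tested and as adjusted over the list alone. The rule for named genes, fixed before the data were examined, took the sort genes Cd34 and Itga6, 8 marker genes in every comparison with 7 Hedgehog and BMP pathway genes for the drugs, the 8 largest positive and 8 largest negative folds among called genes of at least 5 FPKM in the higher population, and up to 4 members of each list with 3 or more called members. Predicted genes, Rik names, pseudogenes, mitochondrial, Xist and Y-linked genes were left out of the largest folds, and so were calls with a value of 0 in 1 of the populations, whose fold is infinite. The rule also asked that the libraries of both groups not overlap and admitted lists by their camera result, and these parts could not be applied without values per library. Some genes that the rule selects are not reported. Genes named outside this rule were chosen after their values were seen. They were Cd74 and Mylpf for CD34a6 against bulk, Hbb-bt and Alas2 for HFSC against bulk, Tcf7l2, Nfatc1, Postn, Id2 and Acta2 for the CD34 fractions, and Sostdc1, H2-Ab1, Acta2 and Gpnmb for the drugs. The closing section names genes of further families chosen in the same way, from 22 families looked at after the data were seen.

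The sets of 200 genes per direction with the largest folds against bulk were followed in the culture tables, and sets of 200 from the CD34 fractions in the drug table, with Cd34, Itga6 and calls of infinite fold left out. Because the labels do not pair CD34a6 and HFSC with the populations, both served as source, giving 10 set tests. Shared calls against bulk are given as counts alone, since both comparisons use the same bulk libraries. Exonic length was the union of exons in GENCODE vM21, known for over 95% of tested genes in each comparison, and the trend with length was removed as the median fold in 20 length bins.

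The list statistic, the length correction and the Benjamini-Hochberg step were tested on simulated data, with normally distributed folds given to the genes of each comparison in their real FPKM bins and 1000 random lists. The authors' own test was not simulated. Of 50 simulated lists of 20 genes with no shift, 4 lay outside the central 95% for CD34a6 against bulk (14095 genes), 5 for HFSC against bulk (13695), 4 for HFSC against CD34a6 (13617), 2 for the CD34 fractions (11066) and 0 for the drugs (11203). At a shift of 0.5 on the log2 scale the numbers were 47, 43, 43, 40 and 48, and at a shift of 1 all 50 lay outside in each comparison. The simulated folds were independent and had the same spread in every comparison. The deposited folds did not, since the central 95% of lists matched to the cholesterol list was -0.98 to 0.33 for CD34a6 against bulk (19 genes) and -0.08 to 0.14 for the drugs (20). The simulated numbers therefore do not say how often such shifts would be found in these data. In each comparison all 200 genes given a p-value under 1e-05 were called, with 6, 9, 10, 21 and 11 other genes. A simulated trend with length of rho 0.45 to 0.46 was within 0.01 of 0 after subtraction.

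The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a fold of at least 2, genes with a mean of at least 5 FPKM, loci with a single symbol, adjustment within each pair, pseudocounts of 0.1 and 0.01, sets of 100 and 500 genes, sets without the suprabasal, cell cycle and other cell type lists, folds with the median of all genes subtracted, and folds with the length trend subtracted.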

Results

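RNA sequencing of mouse epidermal keratinocytes was deposited for 21 libraries in 7 groups of 3. The groups were sorted hair follicle stem cells (HFSCs), total epidermal cells, cultured HFSCs, the CD34+ and the CD34neg alpha-6 integrin+ fractions of 3C cultures, and 3C cultures kept with dorsomorphin or with cyclopamine for 48 h. 3C cultures are cultures in which total epidermal cells were grown for 10 to 14 days, and CD34 and alpha-6 integrin are surface markers used to sort HFSCs of the hair follicle bulge. Dorsomorphin inhibits BMP type I receptors and AMP-activated protein kinase, and cyclopamine inhibits Smoothened, the transducer of Hedgehog signalling. The stated aims were to identify the cell populations that grow in these cultures, and to find early changes with the drug described as depleting HFSCs and with the drug described as enriching them.

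Expression was given as 1 FPKM value per locus and population in 3 tables, so there was no spread between replicates to set beside any value, and every FPKM is the authors' value. The labels do not say whether the replicates of a group came from separate animals or cultures, so the deposited p-values may cover technical spread only. Read depth was unknown, and no counting interval was made. The summed FPKM was 406723, 482175 and 917078 in the populations that the 3-population table calls CD34a6, HFSC and bulk. It was 511143 and 679559 in the CD34+ and CD34neg fractions, and 536270 and 495393 with cyclopamine and dorsomorphin. The labels do not say which of the columns CD34a6 and HFSC holds freshly sorted cells and which holds cultured cells, so the names of the table are used here for both. HFSC below is therefore a column name and does not state that its cells were sorted HFSCs. The closing section gives the values that bear on this. The tables were normalised separately, and levels are compared within a table only. A gene is called higher or lower where its adjusted p in the authors' deposited table was under 0.05.

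Compared with bulk, cells of the CD34a6 column carried more transcripts of the hair follicle bulge and fewer of the differentiating epidermis. Cd34, a sort marker, was at 327 FPKM in CD34a6 and 10.6 in bulk, a 30.9-fold difference, and Itga6, the alpha-6 integrin gene, at 155 and 72.4. Lhx2, a transcription factor of bulge stem cells, stood at 270.3 against 7.91 FPKM, Sox9 at 180.1 against 20.4 and the stem cell receptor gene Lgr5 at 70.5 against 1.88. Krt1 and Krt10, the keratins of suprabasal epidermis, were at 125 and 874 FPKM against 3056 and 25128. Krt15, a bulge keratin, was at 9923 FPKM against 4791 and did not pass the threshold, with an adjusted p of 0.0690 in the authors' deposited table.

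Of 29 tested bulge genes, 25 were higher in CD34a6, 1 was lower and 3 did not pass, among them Tbx1 (361 against 10.3 FPKM), Sfrp1 (482 against 17.4) and Dkk3 (141 against 6.06). Hair germ and outer root sheath genes were higher for 7 of 11, with Shisa2 at 199 against 7.72 FPKM, and lower for 2, with Tnfrsf19 at 3.15 against 37.2. All 11 tested members of the Hedgehog list were higher, including the pathway effectors Gli1 (84.2 against 1.42 FPKM) and Gli2 (20.4 against 0.678) and the inhibitor gene Hhip (10.7 against 0.447). The BMP list had 13 of 17 higher and 1 lower. Its higher members included Grem1 (92.4 against 4.24 FPKM) and Nog (8.66 against 0.434), which encode secreted BMP antagonists. The lower member was the ligand gene Bmp4 (0.981 against 15.3, at a locus that also covers Gm15217). Adhesion and matrix genes were higher for 19 of 21 and lower for 0, with Npnt, a nephronectin gene, at 455 against 16.2 FPKM. Cell cycle genes were higher for 21 of 29 and lower for 0, with Mki67 at 37.8 against 7.48 FPKM and Aurkb at 37.1 against 6.07. Basal epidermal genes were split at 9 higher and 4 lower of 15, with Col17a1 at 1310.3 against 268.6 FPKM and Ly6d at 79.4 against 3550.1. With p adjusted over the list alone, 27 bulge, 24 cell cycle and 7 hair germ genes were higher and 1, 0 and 3 were lower, and the Hedgehog, BMP, adhesion and basal counts were unchanged. The medians of these 7 lists on the log2 scale were 3.00 for bulge, 1.18 for cell cycle, 1.14 for hair germ, 3.02 for Hedgehog, 1.87 for BMP, 2.14 for adhesion and 1.58 for basal genes, each above the 99th percentile of 10000 random lists matched on FPKM.

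Differentiation genes made the other side of the comparison. Of 30 suprabasal genes, 27 were lower in CD34a6 and 0 higher, among them Lor, which encodes the cornified envelope protein loricrin (105 against 5734 FPKM), Lce1a1 (2.01 against 195) and Sprr1a (2.58 against 165). Upper follicle genes were lower for 9 of 12 and higher for 1, with the antimicrobial peptide gene Defb6 at 11.3 against 885 FPKM. Sebaceous genes were lower for 8 of 12 and higher for 0, with Dgat2, an enzyme of triglyceride synthesis, at 19.6 against 469 FPKM. Hair lineage genes were lower for 7 of 17 and higher for 3, with the inner root sheath keratin gene Krt71 at 1.14 against 36.0 FPKM. Cholesterol synthesis genes were lower for 14 of 19 and higher for 0, with Mvk at 21.98 against 198.9 FPKM. Wound keratinocyte genes were lower for 10 of 20 and higher for 3, where Tnc, a matrix glycoprotein gene, was at 136 against 5.10 FPKM and S100a9 was listed at 0 in CD34a6 and at 6.74 in bulk. Immediate early and stress genes were lower for 12 of 17 and higher for 0, with Egr2 at 5.38 against 39.3 FPKM, and the interferon list was lower for 4 of 7 and higher for 0. Adjusted over the list alone, 1 suprabasal gene was higher, 9 sebaceous, 15 cholesterol and 12 wound genes were lower, and the other counts were unchanged. The log2 medians were -4.24 for suprabasal, -2.75 for upper follicle, -1.96 for sebaceous, -1.96 for hair lineage, -1.41 for cholesterol, -1.70 for wound, -1.11 for immediate early and stress and -1.31 for interferon genes, each below the first percentile of matched lists. Fold changes rose with exonic length across 13476 genes (Spearman rho = 0.31, genes not being independent replicates), with a log2 median of -0.62 for genes of up to 1008 nt and 0.52 for genes of 9462 nt or more.

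Markers of cells other than keratinocytes differed as well. Immune markers were lower in CD34a6 for 13 of 15 and higher for 0, with the antigen presentation genes Cd74 at 3.87 against 158.8 FPKM and H2-Aa at 1.06 against 129, and the T cell receptor subunit gene Cd3e at 0.0932 against 14.8. Of the 5 tested erythroid markers 3 were lower, with the globin gene Hba-a1 at 3.91 against 134 FPKM. Fibroblast markers were higher for 3 of 6 and lower for 1, with Col5a1 at 48.4 against 1.73 FPKM and Vim at 5.53 against 56.6. Melanocyte markers were split at 2 higher and 1 lower of 5, endothelial and mural markers at 0 and 1 of 3, and Merkel cell markers at 1 and 0 of 2. The 1 tested muscle marker, Mylpf, was lower at 5.37 against 37.8 FPKM. Of the erythroid markers 4 were lower when adjusted over the list alone, and the other counts were unchanged. The melanocyte median was -0.03 and its mean 0.45.

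The remaining lists were mixed. Wnt genes were higher for 8 of 14 and lower for 3 (log2 median 0.85), TGF-beta genes for 8 and 1 of 13 (0.90), Notch genes for 3 and 3 of 11 (-0.14) and AhR and NRF2 genes for 3 and 3 of 10, where the median was 0.15 and the mean -0.04. Lower members outnumbered higher ones among genes of the endoplasmic reticulum and integrated stress responses (1 higher and 10 lower of 15, median -1.18), p53 targets (1 and 7 of 15, median -0.62) and hypoxia and glycolysis genes (3 and 7 of 20, median -0.50). Cdkn1a, a p53 target that encodes a cell cycle inhibitor, was at 24.8 against 563 FPKM. When adjusted over the list alone, 9 Wnt genes were higher and 4 lower, 4 AhR and NRF2 genes were higher, and the other counts were unchanged. The medians of the Wnt, TGF-beta and stress response lists lay outside the central 95% of matched lists and those of the Notch, AhR and NRF2, p53 and hypoxia lists inside it. With the trend on exonic length subtracted, the Wnt (0.50), TGF-beta (0.47), immediate early (-0.93) and stress response (-0.72) medians came inside that range.

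In all, 3173 genes were higher and 3516 lower in CD34a6 than in bulk among 14441 tested in the authors' deposited table. Among genes at 5 FPKM or more in the higher population, genes with large folds included Il31ra (81.0 against 0.573 FPKM), Galnt15 (16.9 against 0.194) and Kcnn3 (8.14 against 0.134) on the higher side, and the hair keratin Krt27 (0.0946 against 19.6) and Trdc, a gamma-delta T cell receptor gene (0.0379 against 7.70), on the lower side. On GRCm38, Cd34 was given the locus from 194938819 to 195092249 on chromosome 1, a span of 153431 bp that also holds Cd46. Lhx2 lay at 38339281 to 38369733 on chromosome 2, Krt15 at 100131758 to 100135928 and Krt10 at 99385254 to 99389364 on chromosome 11, each of the last 3 at the ends of the annotated gene. The Gli1 locus also covered Arhgap9, and the Lgr5 locus the gene A930009A15Rik, so reads of these pairs may not be separated.

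**Figure D1:**
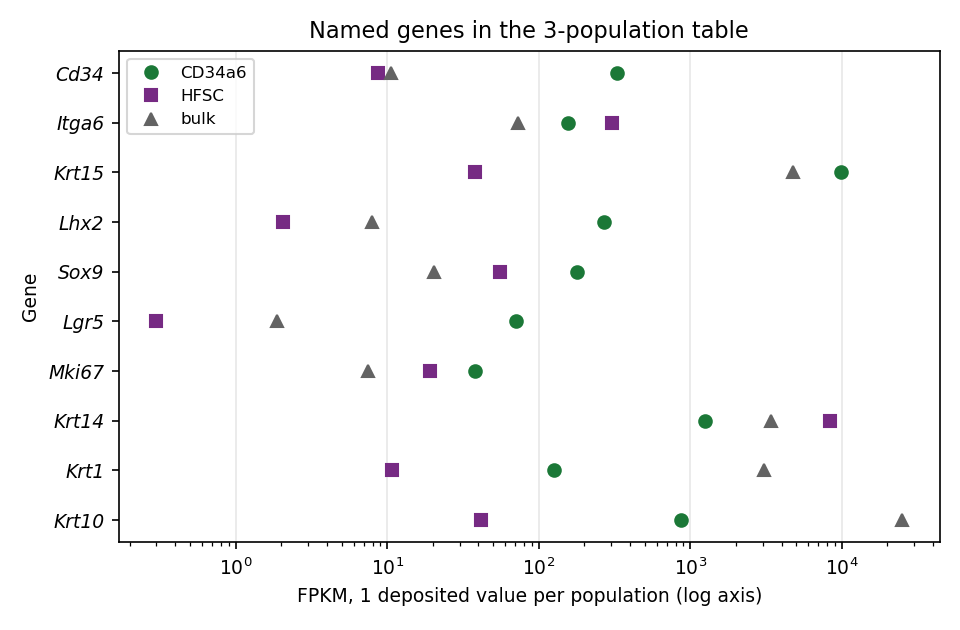
FPKM of 10 named genes on a log axis in the CD34a6 (circles), HFSC (squares) and bulk (triangles) columns, 1 deposited value per population and no error bars. Cd34 stands at 327 FPKM in CD34a6, 8.70 in HFSC and 10.6 in bulk, while Krt14 is highest in HFSC at 8296.

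Compared with bulk, the HFSC column had more wound keratinocyte and basal transcripts, while bulge genes as a group lay within matched lists. Cd34 was at 8.70 FPKM against 10.6 in bulk and did not pass the threshold, while Itga6 was higher at 306 against 72.4. Krt14, the keratin of basal keratinocytes, was at 8296 against 3419.7 FPKM, and Krt15, Lhx2 and Lgr5 were lower at 37.9 against 4791, 2.06 against 7.91 and 0.299 against 1.88. Sox9 was higher at 55.2 against 20.4 FPKM and Mki67 at 19.3 against 7.48. Krt1 and Krt10 were at 10.7 and 41.5 FPKM against 3056 and 25128.

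Wound keratinocyte genes were higher for 17 of 24 and lower for 0, with Krt6b, a keratin of activated epidermis, at 374 against 2.89 FPKM and Sprr1b at 647 against 5.01. Hypoxia and glycolysis genes were higher for 17 of 20 and lower for 0, with the angiogenic factor gene Vegfa at 54.9 against 2.26 FPKM and Car9 at 14.7 against 0.639. Adhesion and matrix genes were higher for 14 of 22 and lower for 3, basal genes for 11 and 3 of 15, with the integrin gene Itgb1 at 285 against 29.9 FPKM, and cell cycle genes for 18 and 0 of 29, with Mcm4 at 30.4 against 9.53. Among stress response genes 11 of 16 were higher and 1 lower, among p53 targets 11 and 2 of 15, with Pmaip1 at 53.6 against 1.89 FPKM, and among TGF-beta genes 8 and 4 of 14. Adjusted over the list alone, 19 hypoxia and 15 adhesion genes were higher and the other counts were unchanged. The log2 medians were 3.25 for wound, 1.92 for hypoxia, 1.87 for adhesion, 1.65 for basal, 0.87 for cell cycle, 1.19 for stress response, 1.20 for p53 and 1.69 for TGF-beta genes, each above the 99th percentile of matched lists.

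Lower groups were the suprabasal (25 of 30 lower and 3 higher), upper follicle (9 of 12 and 1), sebaceous (7 of 12 and 1), hair lineage (5 of 17 and 4), immediate early (10 of 17 and 1) and immune (8 of 15 and 1) lists. Krt77 was at 22.6 against 15602 FPKM, Krt79, a keratin of the upper follicle and sebaceous duct, at 1.17 against 691, and Cd74 at 1.05 against 159. Their log2 medians were -2.48, -2.54, -1.53, -1.87, -0.96 and -3.90, each below the 2.5th percentile of matched lists. Of 28 bulge genes 4 were higher and 11 lower, and the median of -0.14 lay inside the central 95% of matched lists. BMP genes were split at 3 higher and 8 lower of 16, Wnt genes at 3 and 6 of 13, Notch genes at 4 and 4 of 11, Hedgehog genes at 3 and 2 of 10, hair germ genes at 2 and 6 of 11, and cholesterol genes at 1 and 8 of 20. AhR and NRF2 genes were split at 5 higher and 2 lower of 11 and interferon genes at 2 and 3 of 10. Erythroid markers were lower for 2 of 5 and higher for 0, Hbb-bt and Alas2, both listed at 0 in HFSC and at 2.15 and 0.646 FPKM in bulk, with a median of -3.996 below all matched lists. Fibroblast markers were lower for 3 of 5 and higher for 0 (median -0.84, inside the central range), melanocyte markers were split at 2 and 1 of 5, the 2 endothelial and mural and the 2 Merkel cell markers tested were higher and the 1 muscle marker lower. Counts adjusted over the list alone had 8 sebaceous, 6 hair lineage, 12 immediate early and 9 BMP genes lower and 4 BMP genes higher, and were otherwise the same. The melanocyte median was -1.03 and its mean 0.18, with Gpnmb at 40.2 against 0.848 FPKM. Several of these medians depended on the setting. With the trend on exonic length subtracted, the immediate early median was -0.75 and came inside the central range, while those of fibroblast (-1.24), hair germ (-1.04), cholesterol (-0.80) and AhR and NRF2 genes (0.89) lay outside it. With pseudocounts of 0.1 and 0.01 the fibroblast (-2.92 and -4.69), melanocyte (-2.93 and -3.54) and hair germ medians (-1.52 and -1.67) lay below it.

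Among 14035 tested genes in the authors' deposited table, 2664 were higher and 3473 lower in HFSC than in bulk. The median log2 fold of all tested genes was -0.12, and no call changed sign when this shift was taken out. By the same rule, the genes with large folds included the collagenase gene Mmp13 (50.3 against 0.0760 FPKM) and the chemokine genes Cxcl1 (73.6 against 0.125) and Ccl2 (159.7 against 0.433, at a locus that also covers Gm17268) on the higher side, and Ifitm6 (0.131 against 180.1) and Wfdc21 (2.35 against 2006) on the lower side. Folds rose with exonic length here too (Spearman rho = 0.28 across 13117 genes).

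Set against each other, the HFSC column was low in bulge genes and the CD34a6 column low in wound and integrated stress response genes. Cd34 was at 8.70 FPKM in HFSC and 327 in CD34a6, Krt15 at 37.9 and 9923, Lhx2 at 2.06 and 270.3, and Krt14 at 8296 and 1257. Of 29 bulge genes 26 were lower in HFSC and 0 higher, with Col6a1, a collagen gene, at 0.0600 against 118 FPKM and Sfrp1 at 2.73 against 482. Hedgehog genes were lower for 10 of 11 and higher for 0, with Gli1 at 0.283 against 84.2 FPKM, BMP genes lower for 15 of 17 and higher for 1, with Id4 at 2.64 against 78.3, and Wnt genes lower for 9 of 14 and higher for 3.

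Wound keratinocyte genes were higher in HFSC for 17 of 23 and lower for 1. Krt16, a keratin of activated epidermis, was at 1058 against 0.973 FPKM, and the antimicrobial peptide gene Defb14 was at 94.3 and listed at 0 in CD34a6. Hypoxia and glycolysis genes were higher for 17 of 20 and lower for 0, with the glucose transporter gene Slc2a1 at 361 against 32.7 FPKM, stress response genes for 15 and 0 of 16, with Asns, the asparagine synthetase gene, at 174 against 11.9, and p53 targets for 13 and 1 of 15, with Cdkn1a at 225 against 24.8. Cholesterol genes were higher for 11 of 20 and lower for 1, and interferon genes for 6 and 1 of 10. Suprabasal genes went both ways, with 12 higher and 11 lower of 29, where Sprr1a was at 946 against 2.58 FPKM and Calml3 at 12.3 against 456. Fibroblast markers were lower for 5 of 6 and higher for 0, with Col5a1 at 0.729 against 48.4 FPKM. Endothelial and mural markers were split at 2 higher and 1 lower of 4, with Acta2 at 62.1 against 0.289 FPKM, melanocyte markers at 1 and 1 of 4 and Merkel cell markers at 1 and 1 of 3, and no muscle or erythroid marker passed. Cell cycle genes were lower for 11 of 29 and higher for 1. The counts adjusted over the list alone were 18 higher wound genes and 14 higher p53 targets, with no change in the other lists of this paragraph and the bulge, Hedgehog, BMP and Wnt lists.

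The log2 medians were -3.13 for bulge, -2.84 for Hedgehog, -2.04 for BMP, -1.45 for Wnt, -2.60 for fibroblast and -0.35 for cell cycle genes, and 4.35 for wound, 2.54 for hypoxia, 1.91 for stress response, 1.92 for p53, 0.54 for cholesterol and 0.64 for interferon genes, all outside the central 95% of matched lists. Also below it were hair germ (-1.50, 3 higher and 7 lower of 11) and adhesion genes (-0.27, 7 and 9 of 22). For suprabasal genes the median was 0.19 and inside it, as were the medians of upper follicle (3 higher and 5 lower of 10), basal (7 and 4 of 15), Notch (4 and 3 of 10), TGF-beta (7 and 6 of 14), immediate early (8 and 7 of 17) and immune genes (1 and 3 of 6). The TGF-beta median of 0.26 became 1.11 and lay above the range with the trend on exonic length subtracted. Adjusted over the list alone, 9 adhesion genes were higher and 9 immediate early genes lower. Median and mean differed in sign for sebaceous (-0.09 and 0.10), hair lineage (-0.18 and 0.32) and AhR and NRF2 genes (-0.06 and 0.83). In the authors' deposited table, 3514 genes were higher and 4054 lower in HFSC than in CD34a6 among 13962 tested, and 4691 of these calls had a fold of at least 2. Both columns were also compared with the same bulk libraries. Of 13650 genes tested in both, 1319 were higher in both and 2226 lower in both. Another 260 were higher in CD34a6 and lower in HFSC and 174 the reverse. The shared bulk libraries make such counts larger than for separate controls, and the number to be met without any change was not simulated.

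Within the cultures, CD34+ cells had more bulge transcripts than CD34neg cells and less of the suprabasal, wound keratinocyte and interferon transcripts. Cd34, the gene of the sort marker, was at 38.7 FPKM in the CD34+ and 2.26 in the CD34neg fraction, a 17.1-fold difference. Itga6, whose product marked both sorts, was at 346 and 327 without passing the threshold. Krt15 was at 62.4 against 10.7 FPKM, Lhx2 at 6.36 against 0.695, Sox9 at 67.6 against 34.7 and Mki67 at 14.4 against 7.76, all higher. Krt1 was lower at 0.409 against 2.83 FPKM. Krt14 (3378 against 5315 FPKM) and Lgr5 (1.86 against 0.147) did not pass the threshold and Krt10 (0.455 against 1.02) was not tested.

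Of 23 tested bulge genes 14 were higher in CD34+ cells and 0 lower, including the transcription factor genes Tcf7l2 (48.7 against 18.3 FPKM) and Nfatc1 (14.4 against 4.83), the Wnt pathway genes Fzd2 (7.72 against 2.16) and Dkk3 (48.6 against 16.0), and Postn (198 against 72.3). Adhesion and matrix genes were higher for 6 of 20 and lower for 0, with Sparc at 10.3 against 1.43 FPKM and Col4a2 at 7.85 against 2.17, the Col4a2 locus also covering Col4a1. Cell cycle genes were higher for 6 of 29 and lower for 0, with Top2a at 66.1 against 33.3 FPKM, and basal genes were split at 3 higher and 1 lower of 13, with Itgb4 at 151 against 81.9 and Ly6d at 91.1 against 326. Few members passed among hair germ (1 higher and 1 lower of 6), hair lineage (1 and 0 of 5), Hedgehog (1 and 0 of 8), BMP (2 and 0 of 9), Wnt (0 and 0 of 10), Notch (1 and 0 of 8), TGF-beta (2 and 0 of 11) and hypoxia genes (2 and 0 of 19). The BMP members that passed were Id2 at 17.1 against 7.63 FPKM and Fst, the gene of the antagonist follistatin, at 12.2 against 5.21. With p adjusted over the list alone, 17 bulge, 8 adhesion, 7 cell cycle, 4 basal, 2 hair lineage, 3 BMP and 2 Wnt genes were higher and the other counts were unchanged.

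Suprabasal genes were lower in CD34+ cells for 9 of 17 and higher for 0, with Krtdap at 28.8 against 147 FPKM and the desmosomal cadherin gene Dsc1 at 2.42 against 8.44. Wound keratinocyte genes were lower for 9 of 21 and higher for 1, with S100a9 at 9.10 against 45.0 FPKM, the protease inhibitor gene Stfa1 at 123 against 562 and Krt6b at 34.4 against 145. Interferon genes were lower for 3 of 9 and higher for 0, these being Cxcl10 (12.96 against 35.9 FPKM, at a locus shared with Art3), Rtp4 (2.38 against 7.19) and Isg15 (2.09 against 6.81). The cholesterol, p53, immediate early and AhR and NRF2 lists had no member past the threshold, the stress response list had 1 lower of 15, the upper follicle list 1 lower of 4 and the sebaceous list 1 lower of 7. Adjusted over the list alone, 12 suprabasal, 10 wound, 6 interferon and 2 upper follicle genes were lower and the other counts were unchanged. Few markers of other cell types were tested. Of these, 0 of 4 immune, 0 of 2 melanocyte and 0 of 1 muscle markers passed, and no fibroblast, Merkel or erythroid marker was tested. The 1 tested mural marker, Acta2, was higher at 31.8 against 12.9 FPKM.

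**Figure D2:**
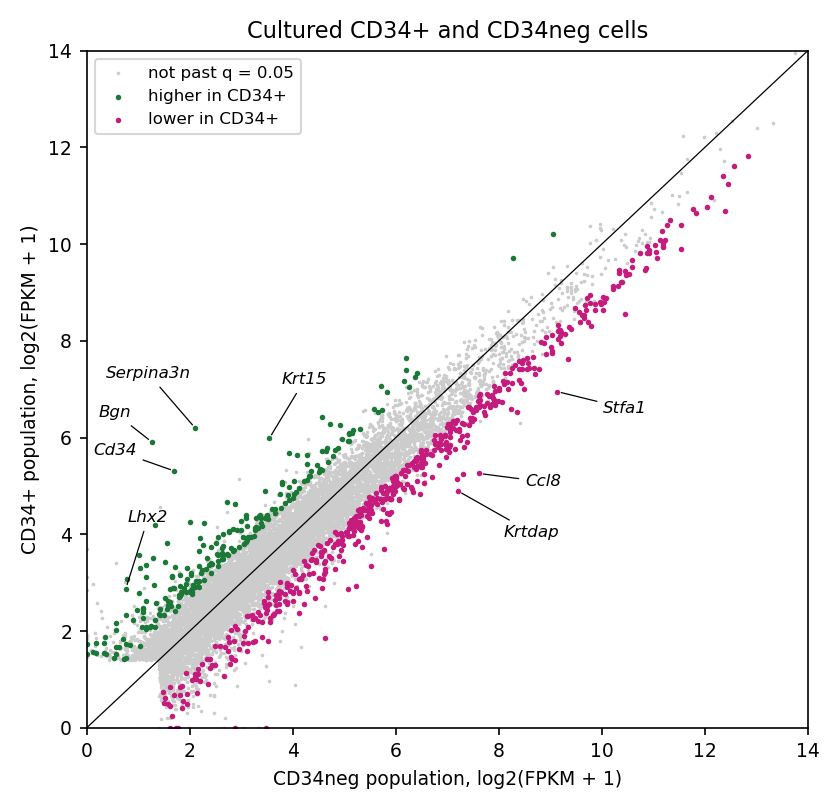
log2(FPKM + 1) of each tested gene in the CD34neg (x axis) and CD34+ (y axis) fractions of 3C cultures, 1 point per gene, with genes past the adjusted p threshold of 0.05 in green (higher in CD34+) and magenta (lower). Higher genes lie above the diagonal line of equal values and lower genes lie below it. Loci of several symbols are left out, so not all of the 236 higher and 536 lower loci called are drawn.

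The list medians on the log2 scale were 1.11 for bulge, 0.63 for hair germ, 0.82 for hair lineage, 0.52 for adhesion, 0.36 for cell cycle, 0.37 for basal, 0.40 for Hedgehog, 0.52 for Wnt and 0.03 for hypoxia genes, all above the central 95% of matched lists. Medians were -0.96 for suprabasal, -0.56 for wound and -1.05 for interferon genes, all below it. BMP genes (0.27), Notch genes (0.30), TGF-beta genes (0.21), AhR and NRF2 genes (0.24), cholesterol genes (-0.24), stress response genes (-0.21), p53 targets (-0.39) and immediate early genes (-0.06) lay inside it. The sebaceous median of 0.03 and mean of -0.11 differed in sign. Folds rose with exonic length (Spearman rho = 0.36 across 10570 genes), with a log2 median of -0.50 for genes of up to 1197 nt and 0.17 for genes of 9791 nt or more. With that trend subtracted the BMP median became 0.70 and left the central range, and the Hedgehog median became 0.29 and entered it.

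Genes chosen from the 3-population table were then followed in the sorted fractions, 200 per direction, with the sort genes left out. Of the genes higher in CD34a6 than in bulk, 50 were tested in the cultures, 23 were higher in CD34+ cells and 0 lower, with a log2 median of 0.82 above all 10000 matched lists. Of those lower in CD34a6 than in bulk, 59 were tested, 27 were lower in CD34+ cells and 0 higher, with a median of -0.88 below all matched lists. Genes chosen from the HFSC column divided less, with 15 higher and 13 lower of 157 for those higher than in bulk (median 0.12, above all matched lists) and 2 and 2 of 20 for those lower than in bulk (median 0.02, inside the central range). With 500 genes per direction this last median was -0.28 and below the range.

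The authors' deposited table had 236 genes higher and 536 lower in CD34+ than in CD34neg cells among 11370 tested. Among genes at 5 FPKM or more in the higher fraction, the higher genes with large folds included the proteoglycan gene Bgn (59.2 against 1.403 FPKM), the protease inhibitor gene Serpina3n (72.4 against 3.31), Cd34 and the proteoglycan genes Gpc6 (17.2 against 1.52) and Cspg4 (10.9 against 1.02). The lower genes with large folds included the chemokine gene Ccl8 (37.3 against 195 FPKM), Calm4 (6.31 against 32.5), Krtdap, S100a9 and the retinoic acid binding protein gene Crabp2 (1.11 against 5.38). On GRCm38, Bgn lay at 73483602 to 73495933 on chromosome X and Ccl8 at 82115185 to 82116799 on chromosome 11, both with the ends of the annotated gene.

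After 48 h, the dorsomorphin and cyclopamine cultures differed in Id gene, Krt15 and hypoxia-associated transcripts, each drug being compared with the other because the drug table holds no untreated cultures. Id1, Id2 and Id3, direct targets of BMP signalling that encode inhibitors of bHLH transcription factors, were lower with dorsomorphin, at 2.502 against 11.9, 1.72 against 4.24 and 2.44 against 11.0 FPKM. Krt15 was lower at 3.61 against 20.6 FPKM, and Krt1 was higher at 12.4 against 6.52. Cd34 was at 6.87 against 11.7 FPKM and did not pass, with an adjusted p of 0.0530 in the authors' deposited table. Itga6 (436 against 390.1), Sox9 (50.6 against 47.2), Lhx2 (1.14 against 1.54), Krt10 (3.62 against 2.89), Krt14 (4484 against 4489) and Mki67 (38.7 against 36.0) did not pass either. Of the Hedgehog target genes, Ptch1 was at 7.20 against 7.47 FPKM and did not pass, and Gli1 (0.0315 against 0.0763) and Hhip (0.0491 against 0.0672) were too low to be tested.

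Of 20 tested bulge genes 4 were lower with dorsomorphin and 0 higher, namely Krt15, Postn (15.3 against 34.9 FPKM), the Wnt inhibitor gene Sfrp1 (6.44 against 9.82) and Gas6 (5.999 against 9.46, at a locus that also covers Tmem255b). The 3 Id genes were the lower members of the 9 tested BMP genes, and 0 were higher. Hypoxia and glycolysis genes were higher for 7 of 20 and lower for 0, among them Adm, the adrenomedullin gene (7.48 against 2.92 FPKM), Ero1l (469 against 254), Egln3 (338 against 199) and Car9 (39.4 against 25.1). Cholesterol synthesis genes were lower for 3 of 20 and higher for 0, with Hmgcs1 at 64.5 against 89.2 FPKM and Acat2 at 26.1 against 37.5. Suprabasal genes were lower for 5 of 25 and higher for 1, with Lce3c at 66.2 against 128 FPKM and Lce1a1 at 23.0 against 41.7. Adhesion and matrix genes were higher for 3 of 21 and lower for 1, with Itga5, a fibronectin receptor subunit gene, at 18.8 against 12.4 FPKM and Tnc at 13.4 against 18.2. Wound keratinocyte genes went both ways, with 4 higher and 2 lower of 23, where the cytokine gene Il24 was at 62.2 against 28.04 FPKM, Mmp13 at 344 against 195 and Stfa3 at 1262 against 1986. When adjusted over the list alone, 10 hypoxia, 5 adhesion and 6 wound genes and 1 BMP gene were higher, 8 cholesterol, 7 suprabasal and 4 wound genes were lower, and the bulge counts were unchanged.

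Fewer members passed in the other lists. Cell cycle (2 of 29) and stress response genes (2 of 16) were higher where they passed, and 1 of 14 p53 targets and 1 of 7 upper follicle genes were higher. Sostdc1, a Hedgehog list member that encodes a secreted BMP and Wnt antagonist, was lower at 53.8 against 144 FPKM and was the sole member of the 8 tested to pass. The sebaceous (1 of 7), hair lineage (1 of 8), hair germ (1 of 7), basal (1 of 14) and AhR and NRF2 lists (1 of 10) each had 1 lower gene. TGF-beta genes were split at 1 and 1 of 11 and immediate early genes at 1 higher and 2 lower of 15, and no Wnt, Notch or interferon gene passed. Of other cell type markers, H2-Ab1 was higher at 17.9 against 9.65 FPKM, Acta2 higher at 6.95 against 3.14 and the melanocyte marker Gpnmb lower at 92.4 against 185, and none of the 3 tested fibroblast markers passed. Adjusted over the list alone, 5 stress response, 3 cell cycle, 2 Notch, 2 p53, 2 TGF-beta, 2 immediate early, 2 immune and 2 fibroblast genes and 1 Merkel cell gene were higher, 4 sebaceous, 2 basal, 3 AhR and NRF2 and 3 immediate early genes were lower, and the other counts were unchanged.

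**Figure D3:**
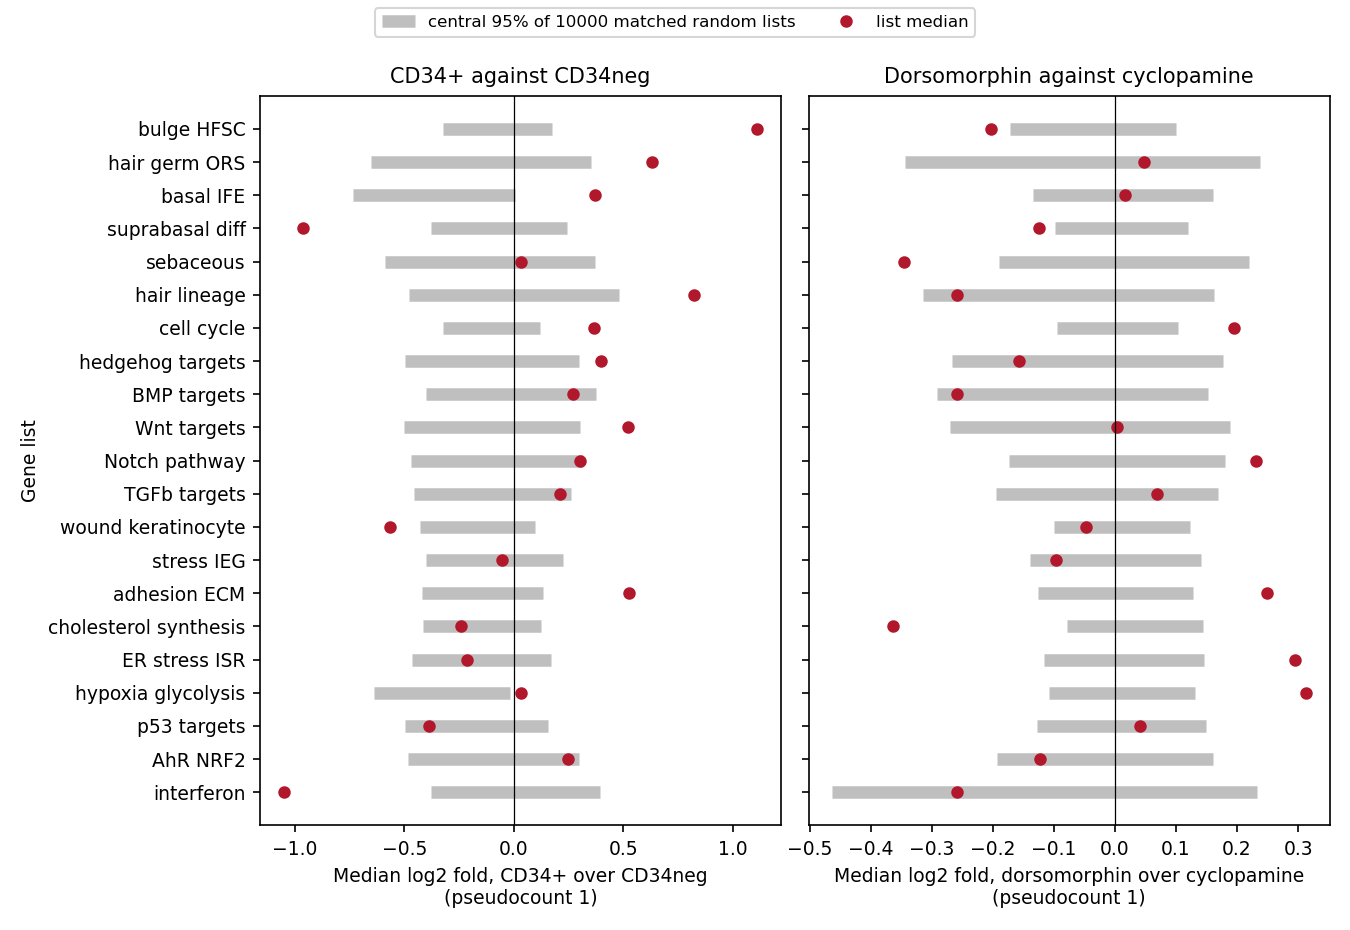
Median log2 fold change (pseudocount 1, x axis) of each gene list with at least 5 tested members, for CD34+ over CD34neg cells (left) and dorsomorphin over cyclopamine (right), as points beside the central 95% of 10000 random lists matched on FPKM (grey bars); the panels have different scales. The bulge median is 1.11 on the left and -0.20 on the right, and the hypoxia and glycolysis median is 0.03 and 0.31.

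The medians of bulge (-0.20), cholesterol (-0.36), suprabasal (-0.12) and sebaceous genes (-0.35) lay below the central 95% of matched lists, and those of hypoxia (0.31), stress response (0.29), adhesion (0.25), Notch (0.23) and cell cycle genes (0.20) lay above it. BMP genes had a median of -0.26 and lay inside, as did Hedgehog (-0.16), Wnt, TGF-beta (0.07), wound, hair germ, hair lineage (-0.26), upper follicle (0.15), basal (0.02), immediate early, p53 (0.04), AhR and NRF2 (-0.12) and interferon genes (-0.26). With the trend on exonic length subtracted the BMP median was -0.27 and fell below the central range, and the suprabasal median was -0.06 and came inside it. Median and mean differed in sign for wound (-0.05 and 0.09) and immediate early genes (-0.10 and 0.02) and lay close to 0 for hair germ (0.05 and -0.00) and Wnt genes (0.00 and -0.05).

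The gene sets of the other comparisons gave small medians here. Genes higher in CD34+ than in CD34neg cells were split at 12 higher and 10 lower of 184 tested (median -0.01, inside the central range), and genes higher in CD34neg cells had 4 higher and 13 lower of 194 (median -0.17, below all matched lists). Of the genes higher in CD34a6 than in bulk, 3 were higher and 5 lower of 46 (median -0.19, below the range, but inside it at -0.23 with 100 and -0.0479 with 500 genes per direction). Of those lower in CD34a6 than in bulk, 5 were higher and 12 lower of 104 (median -0.15, below all matched lists). With the HFSC column as source the medians were 0.11 for genes higher than in bulk (18 higher and 13 lower of 171) and 0.18 for genes lower than in bulk (2 and 3 of 38), both above all matched lists, though the latter was -0.0571 and inside the range with 500 genes per direction. These set tests numbered 10 over both culture tables, because the labels do not say which source column holds sorted HFSCs.

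The authors' deposited table had 145 genes higher and 151 lower with dorsomorphin than with cyclopamine among 11505 tested, and 87 of these calls had a fold of at least 2. The higher genes with large folds included the acute phase gene Saa3 (13.02 against 1.91 FPKM), the placental growth factor gene Pgf (16.5 against 2.57) and the thrombomodulin gene Thbd (5.36 against 1.82). Besides Krt15, Id1 and Id3, the lower genes with large folds included Tslp, a cytokine gene (405 against 1543 FPKM, at a locus that also covers Wdr36), the cornulin gene Crnn (1.52 against 5.43) and Adamtsl5 (8.18 against 25.4). On GRCm38, Id1 lay at 152736251 to 152737410 on chromosome 2, Id3 at 136143497 to 136145755 on chromosome 4 and Id2 at 25093801 to 25096092 on chromosome 12, the ends of Id1 and Id3 being those of the annotated gene.

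**Figure D4:**
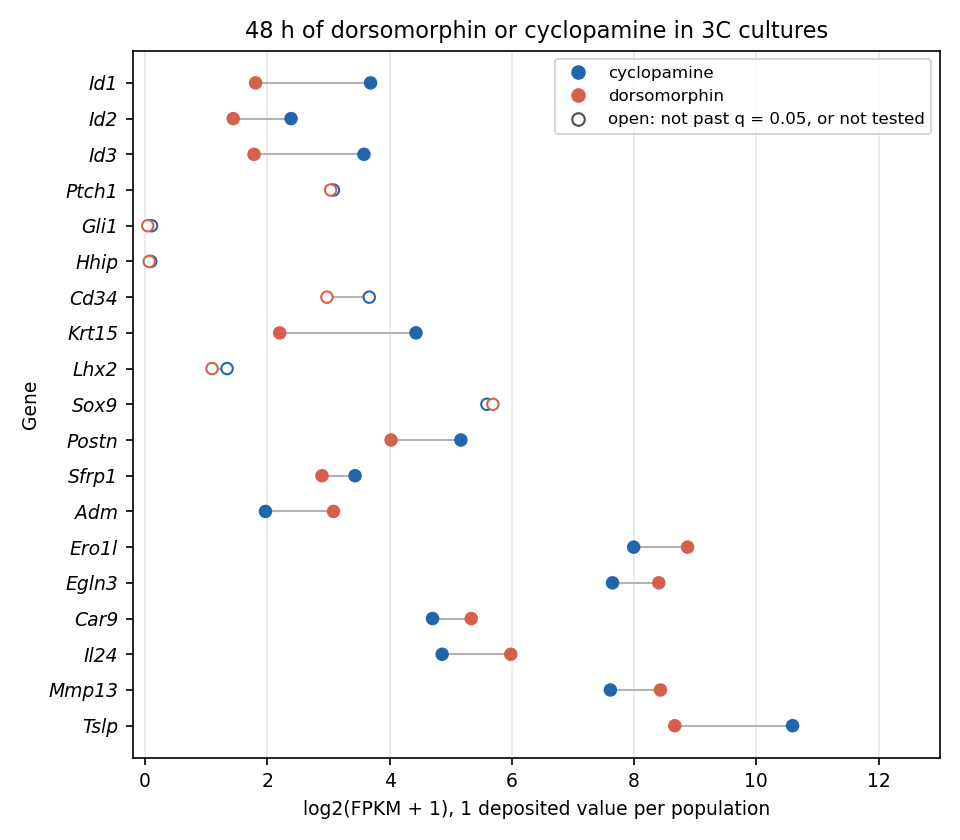
log2(FPKM + 1) of 19 named genes in 3C cultures after 48 h of cyclopamine (blue) or dorsomorphin (red), 1 deposited value per population joined by a line, with open circles for genes that did not pass the adjusted p threshold of 0.05 or were not tested. Id1 is at 11.9 FPKM with cyclopamine and 2.502 with dorsomorphin, and Adm at 2.92 and 7.48.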

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

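The alternatives of single-symbol loci, adjustment within a pair, median subtraction, length trend, pseudocounts for lists and sets, and the drug sets without the named lists were chosen after seeing the data. The others were chosen before the data were examined. Of the 18 alternative counts of calls, 16 stayed within 1.5 times the reported count, and a fold of at least 2 took HFSC against CD34a6 from 7568 calls to 4691 and dorsomorphin against cyclopamine from 296 to 87, since it removes calls of small fold by construction. Both shared-call counts stayed within 1.5 times the reported count at a fold of at least 2, and no call turned sign with the median subtracted. Of the 60 alternative set medians, 56 stayed inside or outside the central 95% of matched lists as reported. With sets of 500 genes, those lower in HFSC than in bulk had a median of -0.28 in the CD34 fractions (reported 0.02) and -0.0571 with the drugs (reported 0.18), and genes higher in CD34a6 than in bulk had medians of -0.23 with 100 and -0.0479 with 500 genes in the drug comparison (reported -0.19), inside the central range. The cause was not tested. Of the 476 alternative list medians, 456 stayed inside or outside as reported, 13 left the central range and 7 entered it, and none of those that moved turned direction. The 7 that entered it did so with the length trend subtracted. Among genes with a mean of at least 5 FPKM, 344 named calls were the same and 1 was not, since Cd34 in the drug comparison passed with an adjusted p of 0.0469 (0.0530 in the authors' deposited table over all genes), where fewer genes were tested. No paired analysis was possible because the tables hold no values per replicate. For the same reason the other test tool, other normalisations, the fit with no low-value filter, pseudocounts for calls, fits of the 2 groups alone, a replicate block, leave-one-out fits, camera with preset or estimated correlation, fry and the simulation of unchanged groups against the shared bulk libraries were not run. Depth was unknown, so a low FPKM such as that of Gli1 or Hhip in the drug cultures sets no limit on expression.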

Other observations

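The gene families and the tests of CD34+ share, scaling, cultured cells and epidermal admixture were chosen after the result was seen, and the tests on transcript length before. Hox genes, which mark position along the body axis, were higher in CD34a6 than in bulk for 12 of 20 tested and lower for 0, with Hoxc8 at 41.8 against 5.06 FPKM and Hoxb6 at 21.2 against 3.08. They were lower in HFSC than in CD34a6 for 14 of 20 and higher for 1, with Hoxa5 at 2.55 against 25.1. Collagen genes were higher in CD34a6 than in bulk for 17 of 27 and lower for 1, with Col18a1 at 224 against 23.4 FPKM and Col6a2 at 36.3 against 1.57. Collagen genes were also lower in HFSC than in CD34a6 for 17 of 27 and higher for 2. Of 12 tested Wnt ligand genes 10 were lower in CD34a6 than in bulk, with Wnt3 at 2.12 against 55.1 FPKM, and 1 was higher, Wnt5b, at 14.1 against 1.32. Cytosolic aminoacyl-tRNA synthetase genes were higher in HFSC than in CD34a6 for 16 of 17 and lower for 0, with Nars at 189.8 against 37.3 FPKM and Gars at 127 against 22.2. None of the 17 passed between the CD34 fractions or between the drugs.

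Chemokine genes were higher in HFSC than in bulk for 8 of 17 and lower for 4, with Ccl7 at 37.2 against 0.239 FPKM and Ccl27a at 12.3 against 429.6. Between the CD34 fractions 4 of 14 were lower in CD34+ cells and 0 higher, with Ccl7 at 63.7 against 133 FPKM and Ccl8 at 37.3 against 195, and between the drugs 3 of 13 were lower with dorsomorphin and 0 higher, with Ccl2 at 105 against 155, Ccl7 at 9.10 against 18.7 and Ccl8 at 5.05 against 13.3. Respiratory chain and ATP synthase genes were lower in CD34+ than in CD34neg cells for 29 of 65 and higher for 0, with Ndufc1 at 53.4 against 141 FPKM, and proteasome genes for 10 of 36 and 0. Folds rose with exonic length in this comparison, and these families were not matched on length. Respiratory chain and ATP synthase genes were also lower in CD34a6 than in bulk (57 of 67, 1 higher) and in HFSC than in bulk (49 of 68, 0 higher).

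Id1, Id2 and Id3 were lower with dorsomorphin than with cyclopamine. A lower share of CD34+ cells would raise the genes of CD34neg cells and lower those of CD34+ cells. The 200 genes highest in each had median log2 folds of -0.17, below all matched lists, and -0.01, inside the range. With the length trend subtracted these medians were -0.09, below all matched lists, and -0.05, inside the range, a smaller contrast. The median of the CD34neg genes lay opposite to such a shift, while bulge genes (median -0.20) and Cd34 (6.87 against 11.7 FPKM, not past the threshold) lay on its side. Ribosomal protein genes, lower in CD34+ than in CD34neg cells for 61 of 81, also had a median of -0.20 between the drugs. Other effects of the drugs on the same genes were not separated, so these medians cannot decide on such a shift. A change in the mixture of these fractions alone could not exceed the ratio between them, and Id1 and Id3 differed 4.76-fold and 4.49-fold between the drugs but 1.22-fold and 1.46-fold between the fractions, which argues against it as the whole cause, while Id2 (2.46-fold and 2.24-fold) is not decided by this bound. With the length trend subtracted the median of the 3 genes was -1.73 on the log2 scale (-1.80 before), which argues against transcript length. A direct effect of dorsomorphin on BMP receptors may explain the difference, stays open as a hypothesis, and was not tested, since the drug table holds no untreated cultures.

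Ribosomal protein genes were lower in CD34+ than in CD34neg cells for 61 of 81 and higher for 0, with Rps14 at 196 against 648 FPKM and a median log2 fold of -1.07. Genes outside the family matched on exonic length and FPKM had a median of -0.54 (range of 95% of matched draws -0.65 to -0.41). Length and level go with about that much of the difference. Exonic length was the union of exons (family median 1739 nt), which can exceed the length of the expressed transcripts. The matching therefore cannot decide on length as the whole cause. The median of all tested genes was -0.0681, so a single factor left in the deposited values does not account for the difference. FPKM values are already scaled per library, so this median cannot decide on a difference between the populations that such scaling removed. Ribosomal protein genes were also lower in CD34a6 than in bulk (69 of 84, 0 higher) and in HFSC than in bulk (58 of 84, 0 higher), where folds rose with exonic length too. Their medians there were -1.99 and -1.21. Lists matched on FPKM were themselves low, with central 95% ranges of -1.31 to -0.59 and -1.03 to -0.29. In HFSC against CD34a6, 63 of 82 were higher and 1 lower. A lower ribosomal protein transcript level in CD34+ cells may remain as a hypothesis, and RNA quality, library batch and annotation of their many pseudogenes were not tested.

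Bulge genes were lower in the column named HFSC than in CD34a6, with a median log2 fold of -3.13. A candidate explanation is that this column holds the cultured cells and CD34a6 the sorted ones, with Cd34 at 8.70 FPKM in HFSC, 10.6 in bulk and 327 in CD34a6. Across 14821 genes, which are not independent replicates, the HFSC column had Spearman rho of 0.80 to 0.85 with the 4 culture columns of the other tables, against 0.67 to 0.69 for CD34a6 and 0.62 to 0.67 for bulk, and its smallest lead was 0.11, as cultured cells would give. The suprabasal median of -2.48 against bulk cannot decide on total epidermal cells within a sorted population, since a small share of them would also leave it below 0. Mixing bulk cells into cells like CD34a6 would give levels between those 2 columns. Krt15 (37.9 FPKM), Lhx2 (2.06) and Lgr5 (0.299) in HFSC lay below CD34a6 (9923, 270.3 and 70.5) and bulk (4791, 7.91 and 1.88). This argues against such a mixture for these 3 genes, while Sox9 (55.2 against 180.1 and 20.4) lay between. Cd34 at 8.70 FPKM, not above bulk, and the closer rank correlation with all 4 culture columns argue against freshly CD34-sorted cells in the HFSC column. The labels do not state the assignment, so the report keeps the names of the table.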
